A study of Homo sapiens with 6 samples.

How the data were processed

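RNA from the human embryonic stem cell line WA09 was measured on 6 Illumina BeadChip arrays, each a genome-wide panel of oligonucleotide probes on beads. Per the labels' protocols, cells were grown on Matrigel in medium conditioned by mouse embryonic fibroblasts and harvested 48 h after transfection with the lipid reagent RNAi-MAX. DNase-treated total RNA was turned into biotin-labelled cRNA. The 3 groups held 2 arrays each: mock transfection, siRNAs against TAZ and YAP (siTAZ/YAP), and siRNAs against TEAD1 to TEAD4 (siTEAD1-4). The sample labels call the control a mock transfection with the reagent, whereas the series design calls it siCntr. The control is called mock here, and no array is known to carry a control siRNA.

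Per the file headers, the non-normalized table gives a signal intensity and a detection p-value for each probe and array. The deposited intensity values reach down to -52.6, and 25.8% to 26.7% of them per array lie below 0, so a background had been subtracted. The deposited detection p-value moves in steps that 290 negative control beads would give. The authors also deposited a normalized table whose unit is not stated. Comparing both tables showed that its values are the log2 of the authors' intensity, floored at 1, plus 1 constant per array that brings every array's median to 5.09. The fit of that formula left a spread of at most 9.997e-09 within an array. The value table of the series matrix holds the same log2 values as the deposited normalized table. The scanner, its software and the background method are not given in the sources used here.

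The text tables list 29376 entries, of which 92 (0.313%) carry no probe identifier and were left out. Of the 29284 identified probes, 27987 have 1 gene symbol in the platform annotation, 0 have several and 1297 have none. Symbols are those of that annotation, and 0 changed on lookup by gene identifier in the gene table supplied. No genome build is named with the data, so no coordinates are given. Genes are named by symbol, and probe identifiers are given for the genes treated most fully.

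Intensities were background-corrected, offset by 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with the negative control distribution inferred from the detection p-values. A probe counted as detected at a detection p under 0.01. Probes detected on at least 2 arrays were kept (13093, of which 12560 had a symbol), and each gene was represented by its brightest such probe, which left 9870 genes. For 2254 of these genes more than 1 probe was detected. Each array had between 11765 and 12970 detected probes. The number of arrays limits the precision of every value.

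Linear models were fitted per gene with lmFit and eBayes of limma over all 6 arrays, with group as the only term, so that all groups shared 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the 9870 genes and a threshold of 0.05 on the adjusted p. Errors given with log2 changes are standard errors from this fit, with 2 arrays per group. Where no array of a group detected a gene, its change is given as "at least N-fold". This sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among detected probes. Nothing in the labels says that replicates came from separate cultures, so p-values of these gene tests measure only the spread between these samples.

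Gene lists drawn up from general knowledge were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 81 tests (27 lists with at least 3 tested genes, in 3 contrasts). At the preset correlation, camera sets the genes of a list against all other genes. Its p-value thus rests on the spread over genes more than between arrays, and can be very small with few arrays. The same lists were tested with an estimated correlation and with fry. A few genes stand on more than 1 list. The groups, contrasts, tests, lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes the siRNA targets and, per knockdown, the 10 largest rises and the 10 largest falls past the threshold with non-overlapping arrays. It adds up to 4 members per list past the threshold, or the 2 brightest where none passed, and CCN2 (CTGF), CCN1 (CYR61), POU5F1, NANOG, SOX2, TBXT (T), MIXL1, EOMES and GSC where tested. Among list members with none past the threshold, only those of lists that passed camera are named.

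Because both knockdowns were compared with the same mock arrays, 100 sets of unchanged groups were simulated against shared controls. With 2 arrays against 2, the smallest two-sided p of an exact permutation test is 0.333, and unchanged genes give non-overlapping groups in 33.3% of cases. The workflow was tested on 20 simulated data sets of 9870 genes for siTAZ/YAP against mock. Noise was drawn independently for each gene and array, with the same spread per gene in all groups, and changes were given to genes drawn at random. With all 6 arrays, 37.9% of genes changed 2-fold and 96.7% of genes changed 4-fold were recovered, and 6.42% of the calls were false. Without the array labelled siTEAD1-4 replicate 1, 29.3% and 96.3% were recovered, and 6.54% of the calls were false. These shares hold for the simulated genes only. They do not show what leaving out that array does in the data, where the siTEAD1-4 arrays differed most from each other. In the data some strongly changed genes had a wide spread: CCN2 (log2 change -3.88 ± 1.13) and CCN1 (-3.76 ± 1.19) did not pass with all 6 arrays. The shifted list was found in 20 of the 20 data sets under both fits, and a list left unshifted was called in 0 and in 1 of them. Because the simulated genes were independent, this does not test the preset correlation of 0.01. The YAP/TAZ-TEAD target list, for example, had an estimated correlation of 0.55 with all 6 arrays. Without the array labelled siTEAD1-4 replicate 1 it was 0.027.

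Alternatives covered the normalization (quantile without background correction, both deposited log2 tables, median centring), the filter on dim probes and the choice of probe. Others covered the replicate number as a block, the arrays in the fit, a spread that follows signal, a minimum fold of 1.5 and each array left out in turn.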

Results

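The data are whole-transcriptome expression profiles of WA09 cells 48 h after mock transfection, after siRNAs against the transcriptional co-activators TAZ (gene WWTR1) and YAP (YAP1), and after siRNAs against their DNA-binding partners TEAD1 to TEAD4. Each group had 2 arrays. Between 40.2% and 44.3% of probes were detected per array, and the median background-subtracted signal ranged from 31.5 to 37.1. Expression values are normalized log2 signals of 9870 genes.

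The siRNA target genes checked the labels. YAP1 (probe ILMN_1709479) had a log2 signal of 11.28 and 10.93 on the mock arrays and of 8.77 and 9.52 on the siTAZ/YAP arrays. The array labelled siTEAD1-4 replicate 1 gave 8.59 for YAP1, whereas siTEAD1-4 replicate 2 gave 11.27. TEAD2 (ILMN_1682781), at 12.46 and 12.63 in mock and 12.75 and 13.11 in siTAZ/YAP, was at 12.90 on the array labelled siTEAD1-4 replicate 1 and at 11.27 on siTEAD1-4 replicate 2. Against the mock mean, TEAD4 lay at -0.54 on the array labelled siTEAD1-4 replicate 1 and at -1.49 on siTEAD1-4 replicate 2, and the siTAZ/YAP arrays lay at -0.60 and -0.54. TEAD3 lay at -1.30 on the array labelled siTEAD1-4 replicate 1, at -2.11 on siTEAD1-4 replicate 2, and at -1.04 and -0.68 on the siTAZ/YAP arrays. TEAD1 and WWTR1 were not above background on any array, so their knockdown could not be checked. The target genes of the array labelled siTEAD1-4 replicate 1 thus go against its label and resemble those of siTAZ/YAP. Over all tested genes this array was closest to siTAZ/YAP replicate 1 (r = 0.990 across genes, SD of the log2 difference 0.295), and it differed more from siTEAD1-4 replicate 2 (SD 0.504). This nearness does not mark the array by itself, since siTEAD1-4 replicate 2 was also closest to the siTAZ/YAP array of its number (r = 0.984, SD 0.365). The mock arrays differed from each other with an SD of 0.444, and the siTAZ/YAP arrays with one of 0.406. Groups follow the labels below, and results are also given without this array.

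**Figure D1:**
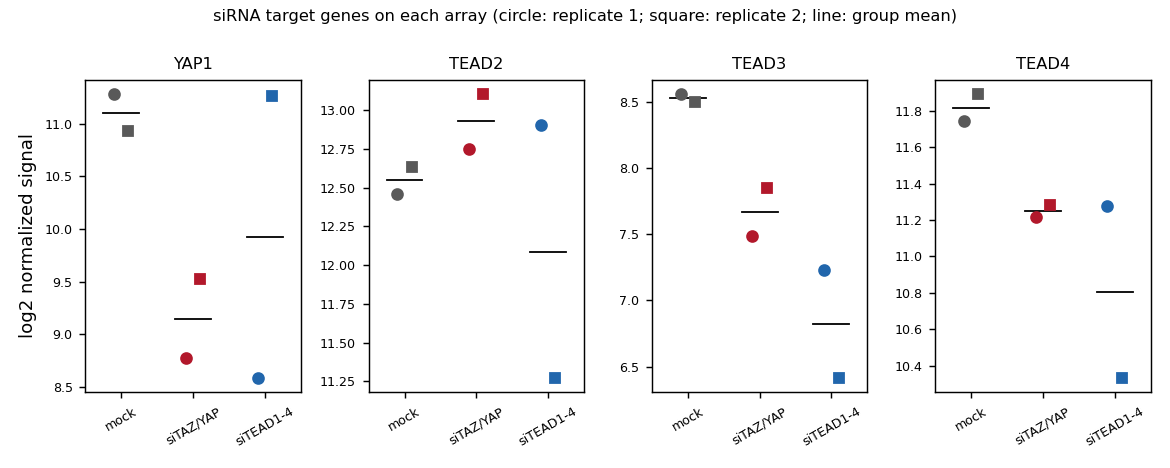
Normalized log2 signal (y axis) of the 4 siRNA target genes above background, in the 3 labelled groups (x axis), with 1 point per array and a line at each group mean. The array labelled siTEAD1-4 replicate 1 (circle) has a YAP1 signal of 8.59 and a TEAD2 signal of 12.90, and siTEAD1-4 replicate 2 (square) has 11.27 for both.

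The comparison of siTAZ/YAP with mock asks which transcripts differ when the co-activators are targeted. The 10 largest falls were in genes of several kinds, among them secreted peptides, transcription factors and a known YAP target. ANKRD1, a nuclear ankyrin-repeat protein and a classic YAP target (ILMN_1716264), fell from a log2 signal of 9.78 ± 0.42 (SD, n = 2) to 5.17 ± 0.03 (SD, n = 2), at least 11-fold (log2 change -4.61 ± 0.55, limma adjusted p = 0.0307). EDN1, the vasoconstrictor peptide endothelin-1, fell at least 7.78-fold (adjusted p = 0.0107), the secreted BMP antagonist GREM1 at least 11.7-fold (adjusted p = 0.0107) and NPPB, the B-type natriuretic peptide, at least 5.42-fold (adjusted p = 0.0108). The long non-coding RNA SFTA1P fell by 4.57 ± 0.60 on the log2 scale. GLIPR1 (at least 8.51-fold), the bHLH repressors HES4 (at least 7.54-fold) and BHLHE40 (log2 -3.50 ± 0.44), the scaffold protein AHNAK (at least 6.94-fold) and the receptor MRGPRF (at least 5.13-fold) complete the 10 largest falls by fitted log2 change. Their order is not certain, since 8 of the 10 were not detected in siTAZ/YAP and have only a lower bound.

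The 10 largest rises included secreted ligands, a hyaluronan synthase and a protease. GDF3 (log2 2.97 ± 0.37, adjusted p = 0.0307) and NODAL (2.17 ± 0.34, adjusted p = 0.0465), both ligands of the TGF-beta superfamily, rose, as did FGF19 (2.33 ± 0.32) and FGF8 (at least 2.55-fold higher). HAS2, which makes hyaluronan, rose by 2.70 ± 0.34, and CTSK, a collagen-degrading protease, by 2.27 ± 0.25. ANKRD35 (2.62), CALB1 (1.72) and CA11 (at least 2.66-fold) also rose. NPY5R was called higher (at least 1.71-fold), but its 2 detected probes disagree in sign. With quantile normalization alone and in the deposited log2 values its log2 change was -0.72. The brightest probe was chosen anew in each of these, so that value may come from the other probe. Of the 11 named and called genes with several detected probes, 10 had all probes on the same side.

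**Figure D2:**
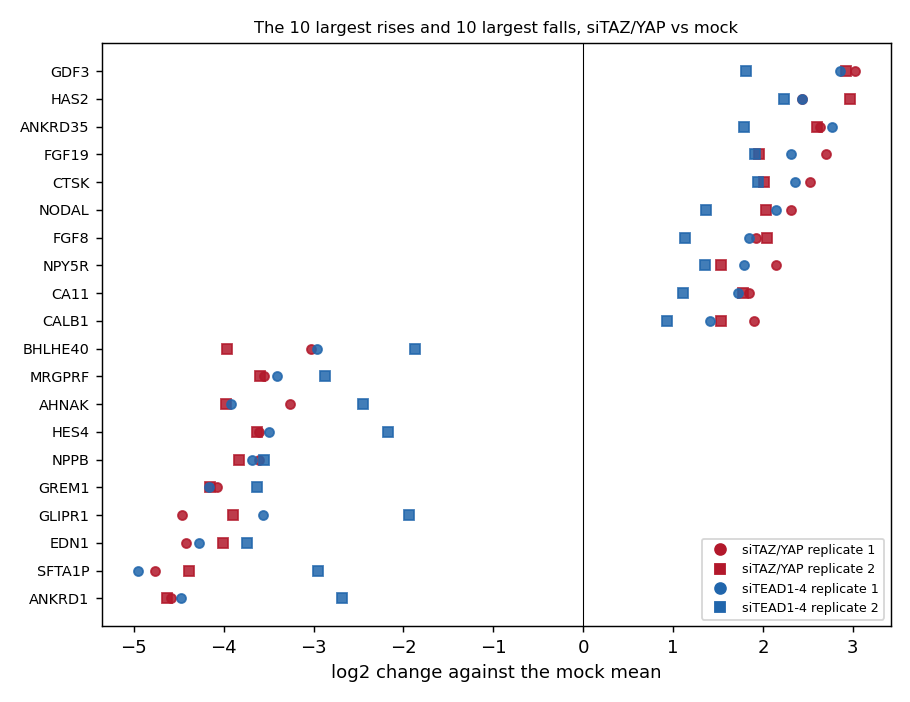
Log2 change against the mock mean (x axis) of the 10 largest rises and 10 largest falls in siTAZ/YAP (y axis), with 1 point per knockdown array. For ANKRD1 the siTAZ/YAP arrays and the array labelled siTEAD1-4 replicate 1 lie between -4.63 and -4.47, and siTEAD1-4 replicate 2 lies at -2.68.

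The gene lists describe broader groups. YAP/TAZ-TEAD target genes, known from other cells, were lower as a group (15 tested, mean log2 change -1.93, camera adjusted p = 1.87e-11; adjusted p = 0.466 with an estimated correlation). Of these, 4 fell (ANKRD1, AXL at -2.57, MYOF at -2.41 and GADD45A at -1.37), 11 did not pass, and 11 fell when adjusted over the list alone. CCN2 (ILMN_2115125) and CCN1 (ILMN_2188264), the best-known targets, had changes of -3.88 ± 1.13 (adjusted p = 0.169) and -3.76 ± 1.19 (adjusted p = 0.199). Without the array labelled siTEAD1-4 replicate 1, whose only part here is in the estimate of the spread, both fell (adjusted p = 0.0160 and 0.0394). The same holds for YAP1 itself (-1.96 ± 0.80, adjusted p = 0.303 with all arrays and 0.0394 without that one).

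Genes of the actin cytoskeleton and serum response were lower as a group (15 tested, mean -1.37, adjusted p = 1.22e-12; adjusted p = 0.466 with an estimated correlation). TPM1 (-1.88 ± 0.22), CALD1 (-1.55), ACTG2 (-1.42) and ACTN1 (-1.21), which encode filament proteins and their binding partners, fell; 11 members did not pass over all genes, and 15 fell when adjusted over the list alone. Extracellular matrix and adhesion genes were lower as a group (15 tested, mean -0.61, adjusted p = 0.000101; 0.466 as adjusted p with an estimated correlation), although 0 passed singly and 4 fell when adjusted over the list alone. Its brightest members, the integrins ITGB1 and ITGB5, had changes of -0.29 and 0.14. Unfolded protein and integrated stress response genes were lower (15 tested, mean -1.01, adjusted p = 6.64e-07; 0.466 as adjusted p with an estimated correlation). Of these, VLDLR, a lipoprotein receptor, fell by 2.14 ± 0.34 on the log2 scale, 14 did not pass, and 8 fell when adjusted over the list alone. The p53 response list was lower (15 tested, mean -0.61, adjusted p = 0.00265; 0.466 as adjusted p with an estimated correlation), with falls in the cell cycle inhibitor CDKN1A (-2.02 ± 0.32) and the death receptor FAS (at least 1.65-fold); 13 did not pass, and 4 fell when adjusted over the list alone. Hypoxia and glycolysis genes were lower (16 tested, mean -0.40, adjusted p = 0.0221; 0.466 as adjusted p with an estimated correlation), with 0 past the threshold singly or when adjusted over the list alone. The glycolytic enzymes GAPDH and ENO1, its brightest members, had changes of 0.19 and 0.13. The call of this group ended without mock replicate 1 (list hypoxia and glycolysis, adjusted p = 0.057) and without siTAZ/YAP replicate 1 (adjusted p = 0.0654).

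Of the lists of early lineages, 2 passed. Mesendoderm and primitive streak genes were higher as a group (6 of 19 listed genes tested, mean 1.33, adjusted p = 0.00184; 0.466 as adjusted p with an estimated correlation). NODAL and FGF8 rose, 4 did not pass, and 4 rose when adjusted over the list alone. EOMES (2.00 ± 0.51, at least 2.03-fold, adjusted p = 0.126) and TBXT (1.26 ± 0.42, at least 1.08-fold, adjusted p = 0.218) passed where either siTEAD1-4 array was left out of the estimate of the spread (adjusted p = 0.0196 and 0.0454). MIXL1 and GSC were not tested because too few arrays detected them. With no filter on dim probes the list had a mean of 0.46 and did not pass (adjusted p = 0.125). Lateral and cardiac mesoderm genes were lower as a group (6 tested, mean -1.12, adjusted p = 0.0316; 0.466 as adjusted p with an estimated correlation). MYL7, an atrial myosin light chain, fell by 2.53 ± 0.25 on the log2 scale and TWIST1 fell at least 3.30-fold; 4 did not pass, and 3 fell and 1 rose when adjusted over the list alone. This call ended with quantile normalization, with the deposited log2 values, with no filter and with probes detected on all 6 arrays (adjusted p between 0.0518 and 0.249), and without mock replicate 1 (0.0516) or siTAZ/YAP replicate 2 (0.0701). G2 and mitosis genes were higher as a group (19 tested, mean 0.32, adjusted p = 0.0028; 0.582 as adjusted p with an estimated correlation), with 0 past the threshold either way; UBE2C and CDC20, the brightest, had changes of 0.22 and 0.22.

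Core pluripotency genes did not pass as a list (26 tested, mean 0.18, adjusted p = 0.0901). Of them GDF3 rose and 25 did not pass; adjusted over the list alone, 4 rose and 1 fell. The 3 central regulators had changes of 0.54 ± 0.19 (POU5F1, adjusted p = 0.253), 0.44 ± 0.16 (NANOG, adjusted p = 0.267) and 0.40 ± 0.19 (SOX2, adjusted p = 0.378). The other lists did not pass either. Single members fell in the neuroectoderm list (SOX3, -2.82 ± 0.32; mean -0.04, median 0.12, adjusted p = 0.915) and the trophoblast and amnion list (IGFBP5, at least 2.19-fold; mean -0.69, adjusted p = 0.157). PDGFRB fell at least 2.18-fold in the fibroblast and mesenchyme list (mean -0.62, adjusted p = 0.0733), and IER3 fell by 1.61 ± 0.17 on the log2 scale in the FGF/ERK list (mean -0.16, median 0.12, adjusted p = 0.494). GDF3 and NODAL rose in the activin/nodal list (mean 0.27, adjusted p = 0.270). No member passed in the remaining lists. Their mean changes were -0.35 (siRNA targets TEAD1-4, adjusted p = 0.268), -0.21 (Hippo pathway components, adjusted p = 0.0676), -0.45 (naive pluripotency, adjusted p = 0.331), -0.30 (neural crest, adjusted p = 0.473) and -0.24 (cholesterol synthesis, adjusted p = 0.0733). They were 0.26 for the BMP response (adjusted p = 0.298), 0.79 for the WNT/beta-catenin response (adjusted p = 0.103), 0.18 for S phase and replication (adjusted p = 0.131) and 0.01 for cytosolic ribosomal proteins (adjusted p = 0.998). The interferon and double-stranded RNA response had a mean of -0.09 (adjusted p = 0.289), immediate early and handling stress genes one of -0.26 with a median of 0.05 (adjusted p = 0.268), and definitive endoderm genes one of -0.18 with a median of 0.40 and a test pointing up (adjusted p = 0.998). The test of the neuroectoderm list pointed up too, against its mean.

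**Figure D3:**
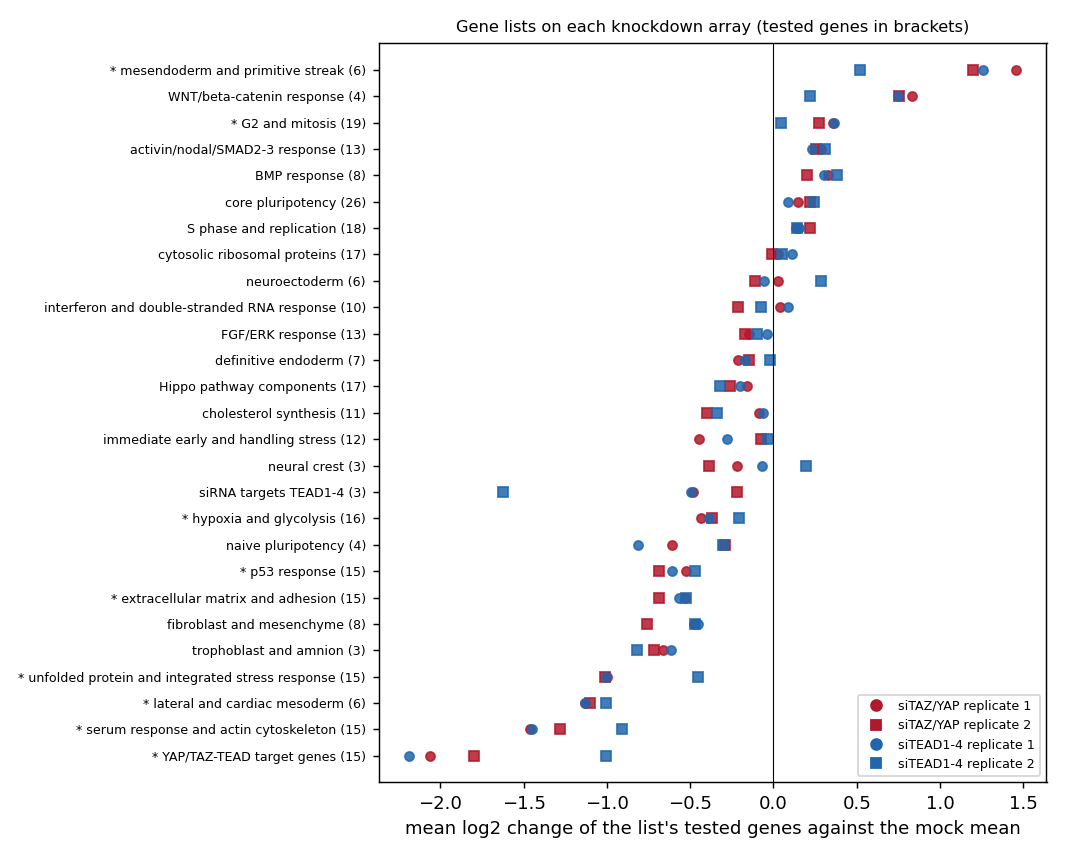
Mean log2 change against the mock mean (x axis) of each gene list (y axis, number of tested genes in brackets), with 1 point per knockdown array. An asterisk marks the 9 lists past the camera threshold in siTAZ/YAP. The YAP/TAZ-TEAD target genes lie at -2.06 and -1.79 in siTAZ/YAP, at -2.19 on the array labelled siTEAD1-4 replicate 1 and at -1.0 on siTEAD1-4 replicate 2.

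In the limma test of siTAZ/YAP against mock, 22 genes rose and 106 fell at an adjusted p under 0.05 (1581 passed unadjusted, where 493.5 would by chance), and 49.4% of genes had non-overlapping groups (33.3% by chance). Without the array labelled siTEAD1-4 replicate 1, 70 rose and 221 fell, all 128 among them. The same numbers followed without siTEAD1-4 replicate 2, since the array then left adds nothing to the spread. No gene passed without mock replicate 1, mock replicate 2, siTAZ/YAP replicate 1 or siTAZ/YAP replicate 2 (unadjusted counts 1061, 1308, 1055 and 1059). Quantile normalization without background correction gave 1 rise and 2 falls, and both deposited log2 tables gave 1 rise and 5 falls. With the replicate number as a block, whose meaning is not stated, 97 rose and 259 fell.

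The comparison of siTEAD1-4 with mock asks the same of the DNA-binding partners, with the reservation that 1 of its 2 arrays goes against its label. The 11 named genes that passed include secreted factors, membrane proteins and enzymes. EDN1 fell at least 7.04-fold (log2 -4.01 ± 0.28), GREM1 at least 10.6-fold (-3.90 ± 0.25), NPPB at least 4.91-fold (-3.62 ± 0.26) and MRGPRF at least 4.64-fold (-3.14 ± 0.23), each with a limma adjusted p of 0.0127. The cytokine IL1A (at least 3.59-fold), the kinase WNK4 (at least 2.84-fold), the caveolar genes CAV2 (-2.53 ± 0.29) and CAVIN1 (-2.30 ± 0.25), the adhesion molecule CADM1 (-2.49 ± 0.25) and the collagen COL11A1 (-2.21 ± 0.25) complete the 10 largest falls by fitted log2 change, and CTSK rose by 2.15 ± 0.25 (adjusted p = 0.0488 for each). On siTEAD1-4 replicate 2 alone, where the first 4 were not detected, EDN1 lay at least 6.99-fold, GREM1 at least 10.5-fold, NPPB at least 4.87-fold and MRGPRF at least 4.61-fold below mock, and CTSK had a change of 1.94. None of the 5 passed on that array alone.

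Of the lists, 2 were higher and 8 lower as groups, and none passed with an estimated correlation (smallest adjusted p = 0.466). The TEAD1-4 targets themselves had a mean of -1.06 (3 tested, camera adjusted p = 0.0146; 0.483 as adjusted p with an estimated correlation). Singly, TEAD3 (-1.71 ± 0.30, adjusted p = 0.0845), TEAD4 (-1.01 ± 0.31, adjusted p = 0.246) and TEAD2 (-0.46 ± 0.50, adjusted p = 0.745) did not pass, whereas YAP1, which these siRNAs do not target, had a mean change of -1.18 ± 0.80 (adjusted p = 0.601). YAP/TAZ-TEAD target genes were lower (mean -1.60, adjusted p = 1.87e-11; 0.466 as adjusted p with an estimated correlation), with 0 past the threshold singly and 11 adjusted over the list alone; CCN2, CCN1 and AXL had changes of -3.53, -2.95 and -1.70. Actin and serum response genes were lower (mean -1.18, adjusted p = 5.67e-12; 0.466 as adjusted p with an estimated correlation; 11 fell adjusted over the list alone), with TAGLN at -2.02 and VCL at -1.02 as examples short of the threshold. Stress response genes were lower (mean -0.73, adjusted p = 3.8e-06; 0.466 as adjusted p with an estimated correlation; 4 fell adjusted over the list alone), as were matrix genes (mean -0.55, adjusted p = 0.000102), p53 response genes (mean -0.54, adjusted p = 0.00135), Hippo pathway components (mean -0.26, adjusted p = 0.0221) and lateral and cardiac mesoderm genes (mean -1.07, adjusted p = 0.0283). For these 4 lists the adjusted p was 0.466 with an estimated correlation, and 0, 2, 1 and 3 members fell adjusted over the list alone. In the mesoderm list ACTC1 and MYL7 had changes of -2.61 and -2.12, and 1 member rose adjusted over the list alone. Mesendoderm genes were higher (mean 0.89, adjusted p = 0.0181; 0.495 as adjusted p with an estimated correlation; 2 rose adjusted over the list alone), with NODAL at 1.75 ± 0.34 (adjusted p = 0.111), EOMES at 1.46 and TBXT at 0.74. G2 and mitosis genes were higher (mean 0.20, adjusted p = 0.0352; 0.613 as adjusted p with an estimated correlation), with 0 past the threshold either way. Besides the other list tests, 6 alternatives ended the G2 call, among them without mock replicate 2 (adjusted p = 0.199), without either siTAZ/YAP array (0.0570 each) and with mean probes (0.0564). POU5F1, NANOG and SOX2 had changes of 0.39, 0.39 and -0.02.

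In all, 1 gene rose and 16 fell (limma, adjusted p under 0.05, with 1299 passing unadjusted). With the replicate number as a block, whose meaning is not stated, 29 rose and 106 fell. Without the array labelled siTEAD1-4 replicate 1, 0 genes passed (smallest adjusted p = 0.106; 900 passed unadjusted), and none passed without either mock array or either siTAZ/YAP array (878 unadjusted without mock replicate 1, 1084 without mock replicate 2, and 1114 without either siTAZ/YAP array). Without siTEAD1-4 replicate 2, 23 rose and 87 fell. On siTEAD1-4 replicate 2 alone, the list means were -1.63 for the TEAD1-4 targets (adjusted p = 6.35e-06), -1.0 for YAP/TAZ-TEAD target genes (1.42e-09), -0.91 for actin and serum response genes (1.16e-09), -0.45 for stress response genes (0.000178), 0.52 for mesendoderm genes (0.0334) and 0.04 for G2 and mitosis genes (0.580). Core pluripotency genes (0.25, adjusted p = 0.0187), BMP response genes (0.38, 0.0193) and cholesterol synthesis genes (-0.34, 0.0222) passed there and not with both arrays. With an estimated correlation none of these lists passed (smallest adjusted p = 0.515). The call of the TEAD1-4 targets ended without siTEAD1-4 replicate 2 (mean -0.50, adjusted p = 0.230), and that of the Hippo list without it (0.144) or without mock replicate 1 (0.141). The mesendoderm call ended without mock replicate 1 (0.124) and with no filter on dim probes (0.201). The lateral and cardiac mesoderm call ended under the same 4 kinds of processing as in siTAZ/YAP (adjusted p between 0.0668 and 0.180).

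Of the 128 genes called in siTAZ/YAP, 17 were also called in siTEAD1-4 as labelled, and 0 without the array labelled siTEAD1-4 replicate 1. These 17 were all the genes called in siTEAD1-4, and each had the same direction in siTAZ/YAP, where independent lists would share 0.172 falling and 0.00223 rising genes. Independent lists are not a full reference, since both comparisons share the mock arrays and the estimate of the spread. The array labelled siTEAD1-4 replicate 1 also resembles siTAZ/YAP, so a shared direction was likely beforehand. The fold changes correlated across genes, which are not independent replicates, with r = 0.901 (simulated 0.500) and a covariance of 0.222 (simulated 0.0373). On siTEAD1-4 replicate 2 alone, r was 0.717 (simulated 0.409) and the covariance 0.169 (simulated 0.0373). With 1 mock array for each knockdown, which shares no control and was added after the results were seen, r was 0.576 and 0.593 the 2 ways round, and 0.514 and 0.343 with siTEAD1-4 replicate 2 alone. Each way sets the knockdowns against mock arrays of different replicate numbers. Deviations shared by arrays of the same number can lower such correlations, by an amount that was not tested. Of the 221 genes lower in siTAZ/YAP without the array labelled siTEAD1-4 replicate 1, 217 lay below mock on siTEAD1-4 replicate 2. Shared mock arrays alone can give a high count. In 100 simulations of unchanged groups, added after the result was seen, the 221 falling genes with the lowest p gave 181 on average (highest 194). Their median change on siTEAD1-4 replicate 2 was -0.34. These simulated genes had no real change, so they do not show how much of the 217 the shared mock arrays explain. The observed median change was -1.07 on siTEAD1-4 replicate 2, -1.74 and -1.73 on the siTAZ/YAP arrays and -1.75 on the array labelled siTEAD1-4 replicate 1. Of the 70 higher genes, 68 lay above mock on siTEAD1-4 replicate 2 (simulated 58.4, highest 66), with a median change of 0.94 there (simulated 0.43) and of 1.59 and 1.47 on the siTAZ/YAP arrays. The simulated arrays were independent, whereas arrays of the same number deviated together in the data. How this would move the simulated values was not tested, so 68 against 66 is not called a clear excess.

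The direct comparison of siTEAD1-4 with siTAZ/YAP asks where the knockdowns differ. The TEAD1-4 targets were lower in siTEAD1-4 (mean difference -0.71, camera adjusted p = 0.00265; 0.466 as adjusted p with an estimated correlation), as were mesendoderm genes (-0.44, adjusted p = 0.00799; 0.466 as adjusted p with an estimated correlation) and G2 and mitosis genes (-0.11, adjusted p = 0.0316; 0.613 as adjusted p with an estimated correlation). Stress response genes (0.28, adjusted p = 0.0127; 0.536 as adjusted p with an estimated correlation), actin and serum response genes (0.19, adjusted p = 0.0217; 0.559 as adjusted p with an estimated correlation) and YAP/TAZ-TEAD target genes (0.33, adjusted p = 0.0221; 0.613 as adjusted p with an estimated correlation) were higher in siTEAD1-4, that is, less lowered from mock. No single gene passed (limma, smallest adjusted p = 1.00; 172 passed unadjusted, fewer than the 493.5 expected by chance), with or without the array labelled siTEAD1-4 replicate 1 (537 unadjusted without it). Adjusted over the list alone, no member passed with all 6 arrays; without that array 8 target genes and 3 stress response genes were higher, and 3 TEAD1-4 targets and 3 mesendoderm genes lower. Without that array the differences widened to -1.27 for the TEAD1-4 targets, -0.81 for mesendoderm genes, -0.27 for G2 and mitosis genes, 0.55 for stress response genes, 0.46 for actin genes and 0.92 for the target genes. Without siTEAD1-4 replicate 2, which leaves only the array whose targets go against its label, none of the 6 lists passed (the TEAD1-4 targets had -0.15, adjusted p = 0.466), and the last 2 turned to -0.08 and -0.26 and the G2 difference to 0.05. Without siTAZ/YAP replicate 1 only the TEAD1-4 targets passed, and without siTAZ/YAP replicate 2 the calls of the TEAD1-4 targets (adjusted p = 0.0742), G2 genes (0.0701) and stress response genes (0.0518) ended. Other processing ended those of actin genes (0.0538 to 0.0584, quantile normalization and both deposited log2 tables), target and stress response genes (0.0713 and 0.0889, probes detected on all 6 arrays) and mesendoderm and G2 genes (0.323 and 0.0615, no filter), and mean probes ended those of target (0.0541) and G2 genes (0.0561).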

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

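The tests of explanations in this part were chosen after the results were seen; the direct comparison of the knockdowns was planned.

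The first pattern is the array labelled siTEAD1-4 replicate 1, on which YAP1 lay at -2.52 and TEAD2 at 0.36 from the mock mean on the log2 scale. A weak knockdown of the TEAD genes under the right label would leave YAP/TAZ-TEAD target genes nearer to mock than on siTEAD1-4 replicate 2, but they lay lower by a mean of -1.18 (SD 1.21 over 15 genes, 14 below 0). That comparison sets 1 array against 1 array, and the target genes are not independent of the low YAP1 that marked the array. An exchange with a siTAZ/YAP array would need a partner with high YAP1, and the highest change of YAP1 among the siTAZ/YAP arrays was -1.58. A candidate explanation that the data leave standing is RNA of cells given TAZ/YAP siRNAs, through a wrong label or an exchanged tube. The change of YAP1, -2.52 against 0.16 on siTEAD1-4 replicate 2, is part of the pattern itself. It is therefore no separate test, and the explanation, found from the same data, stays a hypothesis.

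The second pattern is the lower unfolded protein and integrated stress response list in siTAZ/YAP. The scaling and background correction of the arrays are argued against as the cause, since the weakest mean change over the 3 other normalizations was -1.01. Transfected siRNA against none, whatever its target, stays open: the sample labels name a mock transfection without siRNA, the series design names siCntr, and only a control siRNA would separate it from the knockdown. The interferon and double-stranded RNA response list, which transfected RNA can raise, had a mean of -0.088 over the 10 tested of its 25 genes. Without a known control siRNA that value cannot decide the question. Loss of YAP and TAZ activity stays open as well: siTEAD1-4 replicate 2 lay above the siTAZ/YAP arrays by a mean of 0.55 over the list (SD 0.574 over genes, 11 of 15 above 0), but that is 1 array.

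The third pattern is the higher mesendoderm list. Noise of signals near the background stays open: the lower of the siTAZ/YAP arrays had a mean change of 1.20, and the mock arrays differed by 0.44, but the filter on dim probes may have picked genes by their rise. With no filter the mean was 0.46 (adjusted p = 0.125), although NODAL, detected on all 6 arrays, rose by 2.17 ± 0.34. A share of cells leaving the pluripotent state may contribute, but the median change of the core pluripotency list, 0.21, with members going both ways, leaves this open. Whether the higher list follows from the loss of the co-activators or from transfection of siRNA as such depends on whether the control carried a siRNA, which the labels leave open.

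The direct comparison set 6 lists apart between the knockdowns (siTEAD1-4 minus siTAZ/YAP, mean log2): -0.71 for the TEAD1-4 targets, 0.33 for YAP/TAZ-TEAD target genes, -0.44 for mesendoderm genes, 0.19 for actin and serum response genes, -0.11 for G2 and mitosis genes and 0.28 for stress response genes. All 6 rest on a group with an array that goes against its label, and all 6 were lost with an estimated correlation (adjusted p between 0.466 and 0.613). Without that array, which leaves 1 siTEAD1-4 array, all 6 widened, for example to -1.27 for the TEAD1-4 targets and 0.92 for YAP/TAZ-TEAD target genes. Without siTEAD1-4 replicate 2 instead, these 2 differences were -0.15 and -0.26.

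Outside the genes tested, 533 detected probes have no gene symbol. Of them 8 (1.5%) changed in siTAZ/YAP in limma's test of every detected probe, all lower. Among probes with a symbol 1.31% changed, counting both directions. The largest change, -4.53 ± 0.73 on the log2 scale, was of probe ILMN_1744381 (adjusted p = 0.0477).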

How the results depend on the processing

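Unless said otherwise, the alternatives in this part were planned. Counts are genes past the threshold as higher and lower in siTAZ/YAP, then higher and lower in siTEAD1-4, then in both, against 22, 106, 1, 16 and 17 in the reported analysis. Quantile normalization without background correction gave 1, 2, 1, 0 and 1, and the authors' normalized table and the series matrix's value table gave 1, 5, 1, 0 and 1 each. Median centring gave 26, 105, 0, 4 and 4. With no filter on dim probes the counts were 2, 31, 0, 4 and 4, with more genes tested (19432), and with probes detected on all 6 arrays 12, 55, 1, 11 and 12. The mean of all probes gave 22, 110, 1, 24 and 25, and testing every probe 28, 145, 0, 5 and 5. With only the arrays of the groups compared they were 70, 221, 0, 0 and 0, with a trend in the spread 58, 199, 10, 47 and 55, and with a minimum fold of 1.5 they were 0, 4, 0, 4 and 4. The cause of these differences was not tested. The direct comparison of the knockdowns gave 0 genes under every setting in limma, with 2 to 600 unadjusted.

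The replicate numbers are shared by the groups, and the sample titles share a number within each, so arrays may belong to common sets; what the number stands for is not stated, and with only 2 sets the fit reported left it out. With the replicate number as a block, 97 rose and 259 fell in siTAZ/YAP, 29 rose and 106 fell in siTEAD1-4, and 127 were shared. Deviations of arrays with the same number correlated across genes at 0.388 (mock and siTAZ/YAP), 0.316 (mock and siTEAD1-4) and 0.461 (the knockdowns).

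Without each array in turn, the lone array left in a group is assumed to vary like the other groups. The counts then ranged from 0 to 70 higher and from 0 to 221 lower in siTAZ/YAP, from 0 to 23 higher and from 0 to 87 lower in siTEAD1-4, and from 0 to 108 in both. The correlation of fold changes ranged from 0.717 to 0.921, and over the other planned settings from 0.840 to 0.905. With no shared mock array, added after seeing the data, it was 0.576 and 0.593, and 0.514 and 0.343 without the array labelled siTEAD1-4 replicate 1. Deviations shared by arrays of the same number can lower these values. The siTAZ/YAP calls kept from the 128 numbered 3 with quantile normalization, 6 with either deposited log2 table, 123 with median centring, 33 with no filter, 65 with probes detected on all 6 arrays, 121 with mean probes, 113 with a trend and 4 with a minimum fold; all 128 were kept with a block, with only the groups compared and without either siTEAD1-4 array, and 0 without any other array.

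Over all alternatives, results of named genes past the threshold kept direction and call in 383 of 821 cases, kept direction only in 435 and turned in 3. Named genes not past it stayed so in 1086 of 1190 cases, passed in 88 and turned in 16. Lists past the threshold kept direction and call in 349 of 445 cases, kept direction only in 93 and turned in 3. Lists not past it, followed only in siTAZ/YAP against mock, stayed so in 293 of 320 cases, passed in 15 and turned in 12. Genes not named are not counted, and that limit was set after the alternatives had been run.

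Among the results counted above, turned values were as follows, and the cause was not tested. Lists not past the threshold in siTEAD1-4 or between the knockdowns were not followed and may have turned as well. NPY5R had -0.72 with quantile normalization and with both deposited log2 tables, where the brightest probe was chosen anew and may be its other detected probe. In the same order, the definitive endoderm list had 0.22, 0.22 and 0.22 and the neuroectoderm list 0.77, 0.79 and 0.79. STK4 in siTEAD1-4 had 0.014 with median centring, the interferon list 0.029 with no filter, and in siTEAD1-4 with mean probes SOX2 had 0.0040 and ITGB5 -0.0042. Without each array in turn, values in siTEAD1-4 against mock ranged from -2.52 to 0.16 for YAP1, -1.28 to 0.36 for TEAD2, -1.28 to 0.29 for ZMAT3, -0.16 to 0.12 for SOX2, -0.28 to 0.28 for STK4, -0.0075 to 0.26 for UBE2C, -0.069 to 0.34 for ITGB5, -0.27 to 0.65 for WNT3 and -0.21 to 0.061 for PHGDH. In siTAZ/YAP they ranged from -0.047 to 0.32 for ITGB5, -0.11 to 0.029 for the neuroectoderm list, -0.035 to 0.056 for ribosomal proteins and -0.21 to 0.038 for the interferon list. Between the knockdowns they ranged from -0.26 to 0.92 for YAP/TAZ-TEAD target genes, -0.077 to 0.46 for actin and serum response genes and -0.27 to 0.049 for G2 and mitosis genes.

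No list call held with an estimated correlation (smallest adjusted p = 0.466). With degrees of freedom from so few arrays, calls were lost even where the estimated correlation was below 0. In siTAZ/YAP the hypoxia and glycolysis list, with a correlation of -0.051, went from an unadjusted camera p of 0.00527 to 0.058. With fry 3 lists passed in each knockdown and 0 between them. These were trophoblast and amnion (adjusted p = 0.0141 in both), not called by camera, lateral and cardiac mesoderm (0.0482 in both) and hypoxia (0.0343 in siTAZ/YAP, 0.0482 in siTEAD1-4). In siTAZ/YAP 7 of the 9 camera calls were thus lost, among them YAP/TAZ-TEAD target genes (0.115) and actin genes (0.0607). Of the 17 trophoblast and amnion genes only 3 were tested, and they went both ways. In siTAZ/YAP the log2 changes were -1.63 for TFAP2C, -2.24 for IGFBP5 and 1.80 for ISL1. Lists were not rerun on single probes or with a minimum fold, and a slide block was not run because the files used here name no slide. Signal over background limits TEAD1, WWTR1, MIXL1 and GSC, and for genes detected in 1 group only the fold is a lower bound.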

Other observations

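Genes in this part were chosen after their values were seen. Several pluripotency and signalling genes beyond those named by rule had sizeable changes in siTAZ/YAP without passing limma's test with all 6 arrays. FGF2, the growth factor that sustains human embryonic stem cells, had a log2 change of -2.07 ± 0.56 (adjusted p = 0.147), LEFTY2, an inhibitor of nodal signalling, one of -1.50 ± 0.28 (adjusted p = 0.0665) and CER1, a secreted nodal and BMP antagonist, one of -1.54 ± 0.49 (adjusted p = 0.198). On the other side, DPPA2 had 1.15 ± 0.26 (adjusted p = 0.0984), DPPA3 1.01 ± 0.24 (adjusted p = 0.115) and the secreted WNT modulator SFRP2 1.34 ± 0.23 (adjusted p = 0.0590). ISL1, a cardiac and amnion transcription factor, had 1.80 ± 0.41 (adjusted p = 0.101), TFAP2C, a trophoblast factor, -1.63 ± 0.29 (adjusted p = 0.0596), and the neural adhesion molecule NCAM1 1.62 ± 0.41 (adjusted p = 0.124). Without the array labelled siTEAD1-4 replicate 1, LEFTY2 (adjusted p = 0.0224) and TFAP2C (0.0199) fell and SFRP2 (0.0454) and NCAM1 (0.0219) rose, whereas FGF2 (0.0587), CER1 (0.194), DPPA2 (0.111), DPPA3 (0.130) and ISL1 (0.0695) did not pass.

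Within the stress response list, besides VLDLR, members with larger changes in siTAZ/YAP were DDIT4 (-2.09 ± 0.44), ATF3 (-2.18 ± 0.36), TRIB3 (-1.84 ± 0.41), CHAC1 (-1.54 ± 0.25) and the asparagine synthetase ASNS (-1.39 ± 0.32), which ATF4 is known to activate. None passed limma's test with all 6 arrays (adjusted p between 0.0528 and 0.107), and all 5 fell without the array labelled siTEAD1-4 replicate 1 (adjusted p between 0.0172 and 0.0450). On siTEAD1-4 replicate 2 the changes of these genes from the mock mean were -1.18, -0.86, -0.37, -0.89 and -0.52, in the same order. Of contractile and matrix genes, CNN1 (-3.08 ± 0.62), THBS1 (-2.69 ± 0.56), TAGLN (-2.38 ± 0.63) and COL1A1 (-1.91 ± 0.47) likewise fell without that array (adjusted p = 0.0187, 0.0139, 0.0443 and 0.0163). SPARC (-1.23 ± 0.31), VIM (-1.14 ± 0.21) and the growth factor GDF15 (-2.18 ± 0.49) did not pass either way.

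Of the 92 entries with no probe identifier, 1 was detected on at least 2 arrays; its log2 signal ranged from 6.74 to 7.51 over the 6 arrays.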
